A study of Aedes aegypti with 2 samples.

How the data were processed

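The study isolated nuclei with a commercial nuclei kit from about 30 midguts of 7-day-old Aedes aegypti females of the Higg's White Eye strain, per the labels' protocols. The shared protocol text covers both feeding states, sugar-fed and 24 h after a blood meal, and the libraries were made with the 10x Genomics 3' single-cell chemistry. Each library was deposited as a matrix of UMI counts per gene and barcode, and the counts were used as the authors deposited them. The submitters' processing notes name Cell Ranger 2.1.1 and Seurat 3.1, while the matrices give software version 3.1.0, per the file headers. The genome build and annotation behind the gene identifiers are not given in the sources used here.

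Both matrices were unfiltered: each listed 6794880 barcodes and 19763 genes. A UMI was seen in 2288674 barcodes and 14458 genes in midgut, and in 1742438 barcodes and 14192 genes in midgut_bl. The files give gene identifiers without names. None of the 19763 identifiers matched the RefSeq gene table of assembly AaegL5.0 with 19623 genes (0 matched), so no gene is named or described. For this reason the 32 gene lists, the markers of 12 cell classes, the check of the titles by trypsin genes, the mitochondrial filter and the removal of digestive proteases from the variable genes, all fixed before the data were examined, were not applied. Gene sets are described by rank or ratio, and clusters by number.

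A barcode was called a nucleus where its UMI total reached 10% of the 99th percentile of the 3000 largest barcodes of its library and at least 200 genes were detected. The thresholds were 9182.73 UMIs in midgut and 5429.19 in midgut_bl, and the gene minimum removed 0 barcodes. Scrublet, run per library in scanpy 1.11.5, called 6 doublets in midgut (0.618%) and 5 in midgut_bl (0.327%), and they were kept in the main result. Counts were summed over the nuclei of a library, or of a cluster in a library, and expressed as CPM of that sum. The ratio of midgut_bl over midgut has an exact conditional (Clopper-Pearson) 95% interval, and shares have exact binomial intervals. With 1 library per group, these intervals cover counting error only and no p-value was computed. Log2 ratios used a prior of 0.5 counts.

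Clusters were made in Seurat 5.3.0 under R 4.3.3 from 2000 variable genes, anchors between the libraries, 30 dimensions and a resolution of 0.5. Ratios within clusters were computed for clusters with at least 100 nuclei in each library and genes with at least 50 UMIs in the cluster. Defining genes were the 10 genes with the highest ratio of CPM, after adding 10 to each, over the other nuclei among genes detected in at least 20% of the nuclei of the cluster. Genes per nucleus were thinned to 5000 UMIs. Other computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

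Genes were to be named by a rule fixed before the data were examined: the highest and the lowest ratios among genes with at least 100 UMIs summed over both libraries, an interval wholly beyond 2-fold, and an informative description. No identifier has a description here, so the 2 highest and the 2 lowest by the rest of the rule are named, with a count of 0 over a library's nuclei set to 3 counts for ranking and counts of 1 or more kept as they are, a choice that the rule does not state; the other parts of the rule, which need descriptions or classes, named no gene. The plan took barcodes with 1 to 50 UMIs as free RNA. The plateau between 500 and 1900 UMIs was chosen in their place after the data were examined, because barcodes of nuclei also carried UMIs in the other library, mostly below the plateau. Only the planned subtraction at 10% of nuclear UMIs kept the profile of barcodes with 1 to 50 UMIs, which holds such UMIs. Limits of 16-fold, of 4-fold and of 90% of 1 library, the thinning depth, the sets of 100 genes looked up in neighbouring rows and the clustering without genes that differ between libraries were also chosen after the data were examined.

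The ratio computation was tested on simulated counts for 8366 genes, for the comparison over all nuclei. The counts were Poisson draws from the pooled profile of the real libraries, the model that the interval assumes. They held no variation between nuclei, so the test checks the computation and not the intervals on these data. Of the intervals of unchanged genes, 95.7% held the true ratio. Genes simulated at 5-fold and at 0.2-fold had intervals wholly beyond 2-fold in 100% of cases, those at 2.5-fold in 76% and those at 0.4-fold in 59.6%. Alternatives tried were other rules for calling nuclei, removal of doublets, other scalings, equal weight for each nucleus, subtraction of either profile, a higher UMI minimum, other resolutions, no anchors and the choice of variable genes.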

Results

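RNA of single nuclei was counted in 2 libraries of adult female Aedes aegypti midgut, the part of the gut where a mosquito digests sugar and blood. The study set midguts of females without a blood meal, called unfed in its description and sugar-fed in its protocol, beside midguts of females that had taken blood, and asked how their cell composition and gene expression compared. Its sample titles are midgut and midgut_bl, and they serve as the group names here, because no label states outright which library came from blood-fed females. Each group had 1 library, so no difference between the groups has a replicate check. No test across samples was possible, and all intervals are exact 95% intervals that cover counting error only.

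The midgut library held 173955516 unique molecular identifiers (UMIs, each marking an RNA molecule) and the midgut_bl library 135552252. Calling nuclei by UMI total gave 971 nuclei in midgut and 1527 in midgut_bl. A midgut nucleus had a median of 15458 UMIs and 2674 genes, and a midgut_bl nucleus 7951 UMIs and 2023 genes. Nuclei held 14.4% of the UMIs in midgut and 13.8% in midgut_bl. A further 100966 barcodes in midgut and 99149 in midgut_bl lay in a plateau between 500 and 1900 UMIs, with medians of 1112 and 929 UMIs. These barcodes were taken to hold no nucleus, and their summed counts are called free RNA. Within this range the number of barcodes peaked at 837 to 911 and again at 1519 to 1654 UMIs in midgut. In midgut_bl it peaked at 706 to 769 and again at 1281 to 1395 UMIs. The medians lie between the peaks, and free RNA pools the barcodes of both peaks, whose profiles were not compared. The plateau median equalled 7.19% of the UMIs of a median nucleus in midgut and 11.7% in midgut_bl.

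**Figure D1:**
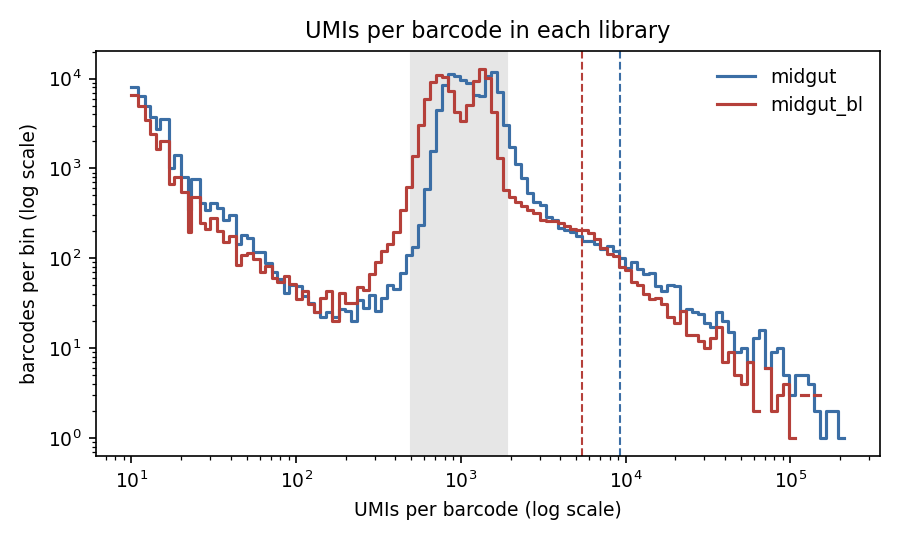
Number of barcodes per bin (y axis, log scale) against UMIs per barcode (x axis, log scale) for the midgut library (blue) and the midgut_bl library (red). The grey band marks the plateau between 500 and 1900 UMIs, and dashed lines mark the calling thresholds of 9182.73 UMIs in midgut and 5429.19 in midgut_bl.

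The first comparison asked how gene expression in the nuclei differed between the libraries. A small set of genes made up much of the RNA in midgut nuclei, and most of that set stood far lower in midgut_bl nuclei, where another set stood in its place. The 3 most abundant genes held 41.1% of the UMIs of midgut nuclei, while the 3 most abundant in midgut_bl nuclei held 18.1%. The gene of rank 2 in midgut held 15.7% of nuclear UMIs there and 0.929% in midgut_bl, a ratio of 0.0592 (0.0590 to 0.0595). In the other direction, the gene of rank 2 in midgut_bl held 5.48% of nuclear UMIs there and 0.0144% in midgut, a ratio of 379.6 (367.4 to 392.3). In free RNA these genes of rank 2 stood higher than in nuclei, at 230018 CPM against 156795 in midgut and at 68380.5 CPM against 54750.4 in midgut_bl. Rank 1 went to the same gene in both libraries, at 19.5% in midgut and 10.2% in midgut_bl.

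Of the 10 most abundant genes of each library, 3 were shared. In midgut the gene of rank 3 held 5.94% and in midgut_bl 0.871% (ratio 0.147, interval 0.146 to 0.147). Likewise, the gene of rank 4 held 2.04% in midgut and 0.453% in midgut_bl (ratio 0.222, interval 0.220 to 0.223). The gene of rank 5 in midgut, at 0.913%, was of rank 4 in midgut_bl, at 2.06%, a ratio of 2.25 (2.24 to 2.27). The genes of rank 5, 6, 7 and 8 in midgut_bl held between 1.18% and 2.04% of nuclear UMIs there, and their ratios were 3847, 137.8, 39.1 and 219.4. Exact binomial limits lay within 0.0205 percentage points of each share of UMIs over all nuclei given here.

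The genes named here were ranked with a count of 0 set to 3 counts, and are known by identifier only, since the gene table used here pairs none of the identifiers in the files with a name. Genes without a UMI in the nuclei of 1 library could rank beyond them by another rule: 7 genes with at least 100 UMIs in midgut (up to 484) had 0 in midgut_bl, and 3 with at least 100 UMIs in midgut_bl (up to 243) had 0 in midgut. AAEL009165 had 51 UMIs in midgut nuclei and 460927 in midgut_bl nuclei, or 2.04 and 24583 CPM (counts scaled to a common total over nuclei). Its ratio was 12076 (9185 to 16220), and it depended on the processing. It was 7322 with equal weight for each nucleus, 5223 with barcodes of at least 1000 UMIs and 3738 with barcodes of at least 500 UMIs. The 51 UMIs lay in 40 of 971 midgut nuclei, with at most 3 in a nucleus. Whether such low counts include reads assigned from the other library was not tested. AAEL010435 had 23 UMIs in midgut and 117851 in midgut_bl, a ratio of 6847 (4563 to 10801), or 3830 at 500 UMIs. At the low end, AAEL010235 had 307 UMIs in midgut and 1 in midgut_bl, a ratio of 0.00435 with a wide interval of 0.00011 to 0.0244; it was 0.000991 at 500 UMIs, 0.00101 at 1000 UMIs and 0.00266 with the 2000 largest barcodes. AAEL022646 had 10686 UMIs in midgut and 39 in midgut_bl, a ratio of 0.00488 (0.00347 to 0.00667), or 0.00964 at 500 UMIs and 0.00914 at 1000 UMIs. In the higher library the CPM in nuclei was below that in free RNA for AAEL009165 (24583 and 27690), AAEL010435 (6285 and 9321) and AAEL010235 (12.3 and 81.4), and above it for AAEL022646 (426.5 and 262.8).

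Over the 8379 genes with at least 100 UMIs summed over both libraries, the median log2 ratio of midgut_bl over midgut was 0.10, with quartiles at -0.55 and 0.65. Ratios lay above 2 for 15.2% of these genes and below 0.5 for 14.6%, as a description of these libraries. Leaving genes above 1% of the UMIs out of the totals shifted all log2 ratios down by 0.34, and the split became 9.57% above 2 and 22.4% below 0.5. Median-of-ratios scaling shifted them down by 0.13. The 102 genes more than 16-fold higher in midgut_bl together held 21.9% of its nuclear UMIs and 0.235% of those in midgut. The 30 genes more than 16-fold lower together held 0.967% in midgut_bl and 16.9% in midgut. Most of both totals was the gene of rank 2 in midgut, which is among the 30 and held 0.929% in midgut_bl and 15.7% in midgut.

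Clustering of both libraries after joining them with anchors gave 8 clusters, numbered 0 to 7, which carry no cell type names because no marker gene could be matched to the identifiers. Each cluster of midgut_bl nuclei held RNA of the genes that were more than 16-fold higher over all nuclei, and in different amounts. Their share of UMIs was 33.2% in cluster 1, 24.0% in cluster 3, 20.7% in cluster 4 and 16.7% in cluster 5. In clusters 0, 2, 6 and 7 it was 13.3%, 12.3%, 11.8% and 11.3%, and in the free RNA of midgut_bl it was 24.7%. In midgut, the same genes held between 0.211% and 0.353% of the UMIs of the 6 clusters with at least 20 nuclei.

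The genes more than 16-fold lower in midgut_bl showed a similar order among the clusters of midgut nuclei. They held 21.3% of UMIs in cluster 1, 20.1% in cluster 3, 15.3% in cluster 4 and 14.0% in cluster 5. Clusters 2 and 6 stood at 7.80% and 7.24%, and the free RNA of midgut at 24.2%. The gene of rank 2 in midgut, which is in this set, alone held 19.9%, 6.99% and 18.7% in clusters 1, 2 and 3. The order among these clusters is therefore largely that of 1 gene. In midgut_bl nuclei the share of the whole set ran from 0.396% in cluster 7 to 1.42% in cluster 1, and was 2.09% in free RNA. Both gene sets were selected on these nuclei, so their totals describe the libraries and do not test them. The exact limits of these shares lay within 0.111 percentage points.

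**Figure D2:**
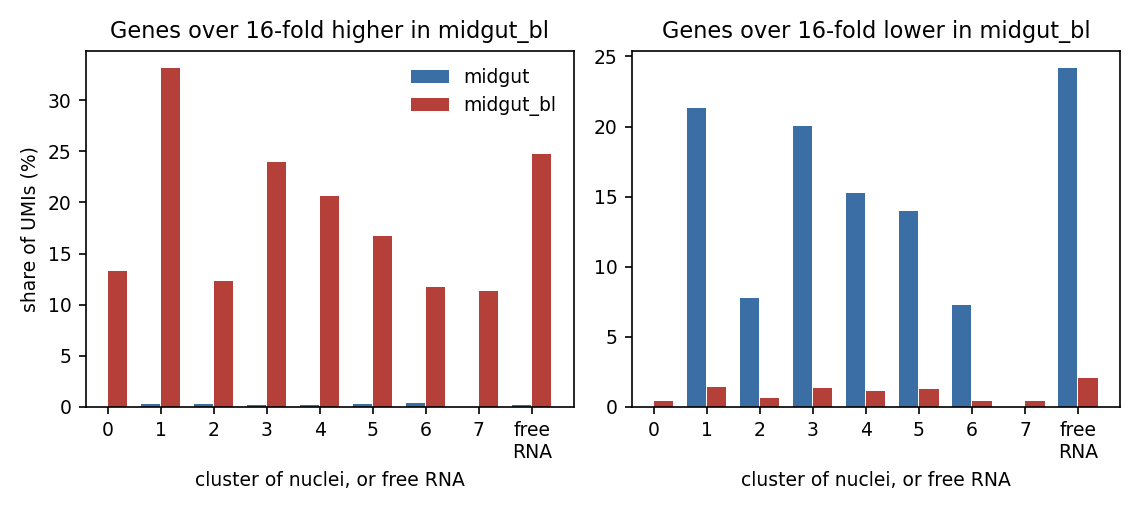
Share of UMIs in percent (y axis) held by the 102 genes more than 16-fold higher in midgut_bl (left) and by the 30 genes more than 16-fold lower (right), in each cluster with at least 20 nuclei and in free RNA (x axis), for midgut (blue) and midgut_bl (red). Among nuclei, cluster 1 had the highest share in both panels, at 33.2% in midgut_bl on the left and 21.3% in midgut on the right. In clusters 1, 2 and 3 most of the share on the right was the gene of rank 2 in midgut.

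The named genes also differed in level between clusters. AAEL009165 stood at 1011 UMIs per nucleus in cluster 1 of midgut_bl, 420.6 in cluster 3, 260.5 in cluster 5 and 258.4 in cluster 4. It stood at 99.3 in cluster 6, 79.7 in cluster 2, 67.8 in cluster 0 and 55.1 in cluster 7, where free RNA in the amount of a plateau barcode would give 25.7. Every called nucleus holds several times the UMIs of a median plateau barcode, so a gene with equal shares in nuclei and free RNA also stands above that amount. Midgut_bl nuclei of cluster 1 were also deeper, with a median of 15194 UMIs against 7172 in cluster 0, and as CPM the gene stood at 45125 in cluster 1 and 8233 in cluster 0. AAEL010435 ran from 23.8 UMIs per nucleus in cluster 7 to 216.6 in cluster 1, against 8.66 from free RNA. AAEL022646 ran from 5.62 UMIs per midgut nucleus in cluster 2 to 19.1 in cluster 1, against 0.292 from free RNA. AAEL010235 stood at 0.126 UMIs per midgut nucleus in cluster 2 and 0.950 in cluster 4, against 0.0905 from free RNA. The value in cluster 4 rests on 114 UMIs in 25 of 120 nuclei, and 1 nucleus held 73 of them, out of 307 UMIs of this gene in all midgut nuclei.

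**Figure D3:**
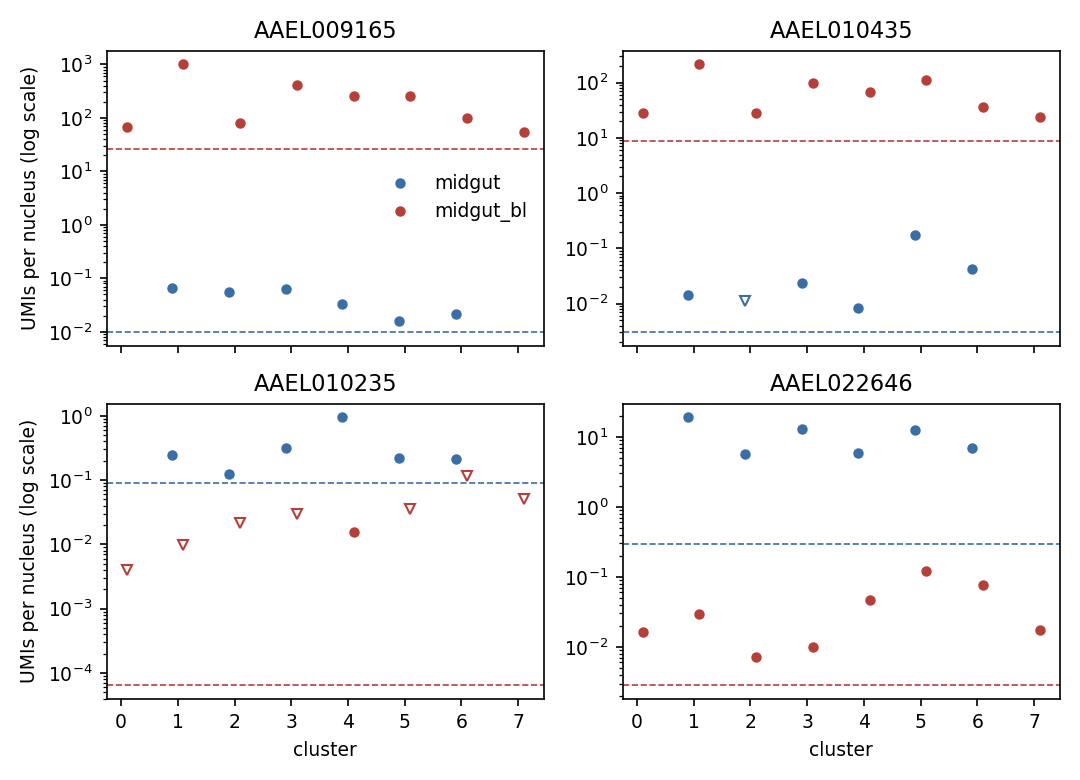
UMIs per nucleus (y axis, log scale) of the 4 named genes in each cluster with at least 20 nuclei (x axis) for midgut (blue) and midgut_bl (red). Dashed lines mark the UMIs that free RNA would give in a plateau barcode, and open triangles mark clusters with 0 UMIs, drawn at the limit of 3 counts over the nuclei of the cluster. AAEL009165 lay above its dashed line in all 8 clusters of midgut_bl.

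The next comparison was made within clusters, between nuclei of the libraries that the anchors had grouped together. Of the 10 defining genes of clusters 1, 2 and 3, 10, 6 and 9 differed by more than 2-fold between the libraries outside the cluster. Nuclei of the libraries within a cluster may therefore still differ in cell type, and the ratios may reflect that in part. Clusters 1, 2 and 3 had at least 100 nuclei in each library, namely 208, 269 and 258 in midgut and 309, 138 and 102 in midgut_bl. The large differences of both genes of rank 2 over all nuclei were also seen in the UMIs of each of them. The gene of rank 2 in midgut went from 19.9% of UMIs to 1.37% in cluster 1, from 6.99% to 0.586% in cluster 2 and from 18.7% to 1.26% in cluster 3. In the other direction, the gene of rank 2 in midgut_bl went from 0.0164% to 9.18% in cluster 1, from 0.0108% to 2.5% in cluster 2 and from 0.0158% to 6.83% in cluster 3. In midgut, the gene of rank 2 there stood below its share of free RNA in each of these clusters. In midgut_bl, the gene of rank 2 there was above its share of free RNA (6.84%) in cluster 1 only. Free RNA caught with the nuclei therefore stays open as a source of part or all of these differences.

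AAEL009165 had a ratio of 23312 (13894 to 42642) in cluster 1, 2556 (1549 to 4569) in cluster 2 and 14374 (8850 to 25149) in cluster 3. In midgut_bl its CPM was above that in free RNA in clusters 1 and 3 and below it in cluster 2. Free RNA stays open for this gene as well. AAEL022646 had a ratio of 0.00237 (0.00108 to 0.00450) in cluster 1. With 1 UMI in midgut_bl in each of clusters 2 and 3, its ratios there were 0.00231 (5.8e-05 to 0.0129) and 0.00161 (4.1e-05 to 0.00896). The gene of rank 5 in midgut was an example of a smaller difference, with ratios of 1.47 (1.44 to 1.5), 1.2 (1.19 to 1.22) and 2.07 (2.03 to 2.12) in clusters 1, 2 and 3.

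Ratios lay beyond 2-fold in either direction for 37.1% of 6204 genes in cluster 1, 25% of 5944 genes in cluster 2 and 33.3% of 6095 genes in cluster 3. Across genes, which are not independent replicates, the log2 ratios of clusters 1 and 2 correlated with a Pearson r of 0.88. For clusters 1 and 3 it was 0.91, and for clusters 2 and 3 it was 0.86. The Spearman rho of these pairs was lower, at 0.781, 0.842 and 0.743. Free RNA of a library can be caught in all its clusters, so these correlations may come from it in part. Ratios had the same direction in clusters 1 and 2 for 79.1% of the genes, in clusters 1 and 3 for 69.2% and in clusters 2 and 3 for 69.4%. The median log2 ratio was -0.29 in cluster 1, -0.10 in cluster 2 and 0.35 in cluster 3.

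Ratios in free RNA followed those in nuclei for many genes. Over the 8379 genes, the log2 ratio in nuclei correlated with the log2 ratio in free RNA at a Pearson r of 0.876 and a Spearman rho of 0.736, across genes. The direction was the same for 74.1% of the genes. Within clusters 1, 2 and 3 the Pearson correlation with the ratio in free RNA was 0.951, 0.846 and 0.896. AAEL009165 had 8.77 CPM in the free RNA of midgut and 27690 CPM in that of midgut_bl.

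**Figure D4:**
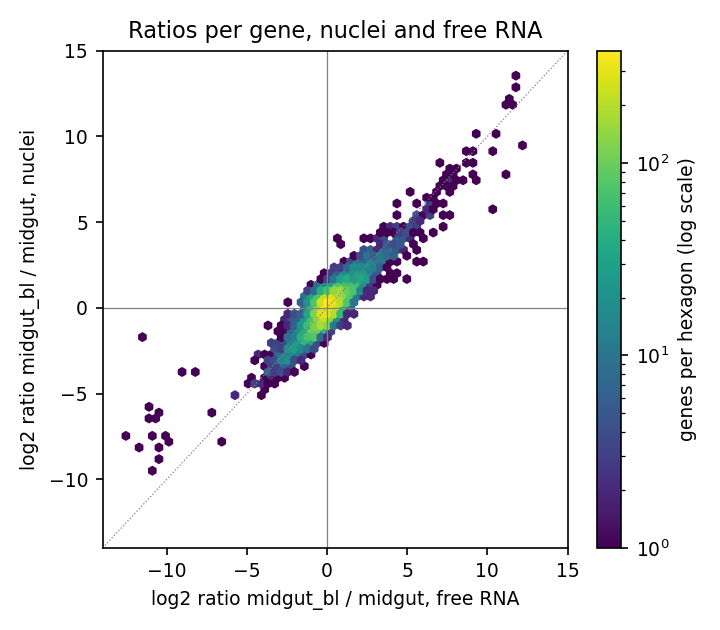
Log2 ratio of midgut_bl over midgut in nuclei (y axis) against the log2 ratio in free RNA (x axis) for the 8379 genes with at least 100 UMIs in nuclei. Colour gives the number of genes per hexagon on a log scale, and the dotted line marks equal ratios; the Pearson correlation across genes was 0.876.

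Cell composition was the other question of the study, and it could be described but not compared. Cluster 0 held 747 midgut_bl nuclei and 5 midgut nuclei, and cluster 7 held 58 and 0, where 0 of 971 nuclei allows a share of up to 0.309% at 3 counts and up to 0.379% by the exact interval. Clusters 4, 5 and 6 held 120, 64 and 47 midgut nuclei and 64, 83 and 26 midgut_bl nuclei. Of the 10 genes that defined each of clusters 0 to 7, 10, 10, 6, 9, 8, 6, 2 and 9 differed by more than 2-fold between the libraries outside that cluster. For this reason the sizes of the clusters are given as the numbers of nuclei behind the other values, and their differences are not read as differences in cell composition.

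Over all nuclei, the order of the libraries in genes per nucleus changed after thinning. At full depth the median was 2674 in midgut and 2023 in midgut_bl, and after thinning every nucleus to 5000 UMIs it was 1250 (quartiles 976 and 1676) in midgut and 1636 (quartiles 1286 and 1700) in midgut_bl, with 0 nuclei left out. Within cluster 1 the thinned medians were 996 and 943, within cluster 2 they were 1735 and 1717.5, and within cluster 3 they were 961.5 and 1242. In clusters 1 and 2 midgut was also higher at full depth (2515 against 1743 and 2890 against 2044.5). The order did not change there. Within clusters 4, 5 and 6 the thinned medians were 1369, 1207 and 1777 in midgut and 1518, 1347 and 1792.5 in midgut_bl. Cluster 0, with 747 midgut_bl nuclei and 5 midgut nuclei, had a thinned median of 1664 in midgut_bl and weighs on the value over all midgut_bl nuclei.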

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

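All tests in this part were chosen after the data were examined, except the share of cluster 0 above 1.5 times the higher calling threshold.

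Most of the RNA counted in both libraries lay outside the called nuclei. The plateau barcodes between 500 and 1900 UMIs, which no comparison between nuclei in the main result uses, held 68.5% of the UMIs of midgut and 74.7% of those of midgut_bl. A further 8089 barcodes in midgut and 3817 in midgut_bl had more than 1900 UMIs without reaching the calling threshold. Their summed log2 CPM correlated across genes with those of the nuclei at 0.991 in midgut and 0.994 in midgut_bl, and with those of the plateau at 0.877 and 0.801.

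The ratios in nuclei followed the ratios in free RNA (Pearson r of 0.876 across genes), which could come from free RNA caught with the nuclei. For 605 of the 758 genes beyond 4-fold (79.8%, interval 76.8% to 82.6%) the share of UMIs in the higher library was larger in the nuclei than in free RNA. An excess beyond counting error cannot come from any amount of free RNA with the plateau profile. Any excess was counted here, however small, without an allowance for counting error per gene. Free RNA thus stays open for the other 153 and for genes with a small excess among the 605. Among the 153 are AAEL009165, AAEL010435, AAEL010235 and both genes of rank 2. In cluster 1 of midgut_bl the level was above that in free RNA for AAEL009165 (45125 CPM against 27690) and AAEL010435 (9665 against 9321). There the gene of rank 2 in midgut_bl was above it too (9.18% of UMIs against 6.84%). In all other clusters of midgut_bl AAEL010435 was below free RNA (2762 to 6629 CPM). AAEL009165 was also above free RNA in cluster 3 (27879 CPM) and below it in the others. The pooled plateau profile cannot give the excess in cluster 1 in any amount. But that reading rests on the cluster with the highest level and on 1 pooled profile, so free RNA stays open for these genes. A response of the midgut cells to feeding, seen in nuclear and in released RNA alike, stays open as an untested biological explanation.

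Cluster 0 held almost only nuclei of the midgut_bl library, and a candidate explanation is the lower calling threshold there. Among the 586 midgut_bl nuclei at or above the midgut threshold, 177 (30.2%, interval 26.5% to 34.1%) were still in cluster 0, against 0.515% of midgut nuclei, and above 1.5 times the higher threshold 42 of 309 midgut_bl nuclei (13.6%, interval 9.97% to 17.9%) and 0 of 583 midgut nuclei were, so the share falls with depth but the threshold alone does not account for it. The 10 defining genes held a median of 29.9 times (14.9 to 85.5) their share of free RNA, but they were picked for being high in this cluster, so free RNA stays open. Within clusters 1 to 3 the same genes were also higher in midgut_bl, with a median log2 ratio of up to 4.86 against 6.32 for cluster 0 over midgut, and a library-wide shift of these genes and a state of some cells cannot be told apart with 1 library per group. Feeding state, the difference the study names, stays untested.

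Barcodes of nuclei also carried UMIs in the other library: a median of 73 UMIs for barcodes of midgut nuclei in midgut_bl and of 46 for barcodes of midgut_bl nuclei in midgut, among the 912 and 1480 that lay below the plateau there. Of these barcodes 100% had a UMI in the other library, against at most 24.0% of random barcodes. The random barcodes were drawn only from those without a UMI in the library of the nuclei, which can lower that share. Most of the barcodes listed for each library had no UMI there, so the 100% still argues against barcodes shared by chance. A candidate explanation is reads of 1 library assigned to the other. The UMIs there rose with the UMIs of the same barcode in its own library (rank correlation of at least 0.90). Of the gene and barcode pairs, 93.6% and 89.7% were present in the own library, against 79.6% and 77.1% after shuffling barcodes. The shuffle did not match barcodes by UMI total, so depth may account for part or all of that drop. The UMIs found there amounted to 0.475% of the own UMIs for midgut and 0.590% for midgut_bl; no biological explanation was tested.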

How the results depend on the processing

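The settings chosen after the data were examined were the midgut threshold in both libraries, subtraction of the plateau profile, totals without genes above 1% and clustering without genes that differ between libraries. No direction of a named gene changed under any setting, and the cause of each shift below was not tested unless the setting fixes it. Not run or void were the alternatives on gene lists, mitochondrial share and digestive proteases, since no identifier was matched, and clustering of barcodes with at least 500 or 1000 UMIs, most of which are plateau barcodes. Subtraction at 10% took off the profile of barcodes with 1 to 50 UMIs, which includes UMIs at barcodes of nuclei of the other library, so its values do not stand for removal of free RNA. No paired analysis was possible because each group has 1 library.

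Barcodes counted as nuclei numbered 110026 in midgut and 104493 in midgut_bl at 500 UMIs, and 71595 and 51605 at 1000 UMIs. Most of these were plateau barcodes, taken elsewhere to hold no nucleus, and no gene minimum was applied. The number was 2000 in midgut with the 2000 largest barcodes, and 586 in midgut_bl at the midgut threshold. Median UMIs per barcode so counted in midgut were 1161 at 500 UMIs, 1459 at 1000 UMIs and 8945 with the 2000 largest barcodes. In midgut_bl they were 983, 1354 and 6829.5, and 14153.5 at the midgut threshold.

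The median log2 ratio over genes was 0.19 at 1000 UMIs, 0.056 with the 2000 largest barcodes, -0.028 with median-of-ratios scaling, 0.075 with equal weight per nucleus, -0.24 without genes above 1% in the totals and 0.23 over genes with at least 500 UMIs. Ratios above 2 made up 16.5% at 1000 UMIs, 13.8% with the 2000 largest barcodes, 12.8% with median-of-ratios scaling, 9.57% without genes above 1% and 19.7% over genes with at least 500 UMIs. Ratios below 0.5 made up 10.6% at 500 UMIs, 10.2% at 1000 UMIs, 17.3% with median-of-ratios scaling, 15.8% with equal weight, 16.1% after subtraction at 10%, 22.4% without genes above 1% and 13.2% over genes with at least 500 UMIs.

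The correlation of ratios in nuclei and free RNA was 0.971 at 500 UMIs and 0.954 at 1000 UMIs, where the called barcodes include the plateau. It was 0.888 with the 2000 largest barcodes, 0.857 with equal weight, 0.855 after subtraction at 10%, 0.861 after subtracting the plateau profile, and 0.914 over genes with at least 500 UMIs.

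Clusters with 90% of 1 library held 0.515% of midgut nuclei and 52.7% of midgut_bl nuclei in the main result. Without anchors they held 98.4% and 88.0%, and no ratio within clusters 1 to 3 could be computed. Above 1.5 times the higher threshold they held 0% and 15.2%, at the midgut threshold 32.8% of midgut_bl nuclei, and with clusters made without differing genes 0% of either. That last value largely follows from the setting, which removes genes for differing between the libraries, and 10, 8, 6, 9, 6 and 6 of the 10 defining genes of its clusters still differed by more than 2-fold. There the cluster that took most of cluster 7 had a log2 share ratio of -0.68, the reverse in sign of the main result. It held 53 nuclei of cluster 7 and 325 of cluster 2, so its ratio does not describe the nuclei of cluster 7. Under the same setting, the cluster that took most of cluster 0 held 8.55% of midgut nuclei and 47.0% of midgut_bl nuclei. At the midgut threshold these shares were 8.55% and 26.8%.

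Genes beyond 2-fold within cluster 1 made up 35.2% at resolution 0.3, 42.6% at resolution 1.0, 39.2% with the 2000 largest barcodes, 35.6% with clusters made without differing genes, 40.2% after subtraction at 10%, 34.6% with median-of-ratios scaling and 41.7% without genes above 1%. After that subtraction and those scalings they made up 26.7%, 23.8% and 26.6% in cluster 2, and 35.1%, 30.8% and 30.7% in cluster 3.

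Correlations of the log2 ratios of clusters 1 and 2 were 0.896 at resolution 0.3, 0.857 at resolution 1.0, 0.897 without doublets, 0.889 with the 2000 largest barcodes, 0.904 with clusters made without differing genes, 0.863 with equal weight, 0.865 after subtraction at 10% and 0.858 after subtracting the plateau profile. For clusters 1 and 3 they were 0.908 and 0.919 at the lower and higher resolution, 0.922 with the 2000 largest barcodes, 0.903 without differing genes, 0.891 with equal weight and 0.908 after subtracting the plateau profile. For clusters 2 and 3 they were 0.867 at resolution 0.3, 0.871 without doublets, 0.884 without differing genes, 0.836 with equal weight, and 0.867 after subtraction at 10% and 0.846 after subtracting the plateau profile.

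The ratio of AAEL009165 ranged from 3738 to 14044 and that of AAEL010435 from 3830 to 7207 over 8 settings. The ratio of AAEL010235 ranged from 0.000991 to 0.00584 and that of AAEL022646 from 0.00385 to 0.00964 over the same 8 settings. Subtraction at 10% is left out of these ranges, because it left 0 UMIs in the lower library for each of the 4 genes, an effect of that profile, which holds these genes at far higher levels there than the plateau does; with the plateau profile the ratios of the lowest pair were 0.00569 and 0.00461. Both genes with the highest ratios remained the highest pair in all settings except subtraction at 10%, where 1 did. Of the lowest pair, ranked with a count of 0 set to 3 counts, 0 remained at 500 and at 1000 UMIs, and 1 with equal weight, with subtraction at 10% and over genes with at least 500 UMIs. AAEL010235 rests on 1 UMI in midgut_bl.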

Other observations

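The values in this part were all computed after the data were examined. Cluster 0 of midgut_bl resembled cluster 2 most closely among the clusters of both libraries. Its summed log2 CPM correlated across genes with those of cluster 2 at 0.950 in midgut_bl and 0.757 in midgut. The correlations with clusters 6, 7 and 4 of midgut_bl were 0.939, 0.922 and 0.911, and with clusters 3, 1 and 5 they were 0.692, 0.655 and 0.627. Clusters also differed in how closely they resembled the free RNA of their own library. In midgut_bl the correlation was 0.951 in cluster 1, 0.882 in cluster 5, 0.876 in cluster 3 and 0.760 in cluster 4, and 0.634, 0.632, 0.605 and 0.581 in clusters 0, 2, 6 and 7.

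The gene of rank 5 in midgut nuclei and of rank 4 in midgut_bl nuclei was the exception among abundant genes in being far more abundant in nuclei than in free RNA. Its CPM in nuclei was 10.4 times that in free RNA in midgut and 21.1 times in midgut_bl. For the other 9 of the 10 most abundant genes of each library this value lay between 0.674 and 1.05 in midgut and between 0.439 and 0.888 in midgut_bl. Within clusters, its share of UMIs was 0.231% in cluster 1, 2.73% in cluster 2 and 0.341% in cluster 3 of midgut, and 0.341%, 3.28% and 0.707% in midgut_bl.

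Genes with extreme ratios often stood next to each other in the order of the files, which is not stated to be genomic order. Among the 100 genes with the highest ratios, 15 pairs were neighbours in the list of 8379 genes. Random lists of 100 genes gave a mean of 1.17 such pairs, and at most 7 in 10000 lists. The 100 genes with the lowest ratios had 8 neighbouring pairs, against a mean of 1.16 and at most 7 in random lists.

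The smallest barcodes of midgut, with 1 to 50 UMIs, held AAEL009165 at 3426 CPM, against 8.77 CPM in the plateau barcodes of the same library.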
